A study of Rattus norvegicus with 21 samples.

How the data were processed

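RNA from 21 samples of the rat insulinoma line INS-1 was measured on Affymetrix arrays, 1 array per sample. Per the labels, untransfected cells and the lines pcDNA (empty vector) and pCTSH#1 (cathepsin H, CTSH) made 7 groups of 3 arrays, and the cytokines were 150 pg/ml IL-1β and 5 ng/ml IFNγ for 6 or 16 h. The labels number the replicates but do not say whether they are separate cultures, so the p-values measure the spread between these arrays.

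The deposited values are log2 probe set intensities made by the authors with RMA (background correction, quantile normalization and summary per probe set); RMA, affy and limma are named per the submitters' processing notes, without versions. The values ran from 2.77 to 13.99 over all arrays and were used as deposited. Of the 31137 probe sets, 95 array controls were set aside and 31042 were tested, with no filter on dim values. The annotation gave 1 gene symbol for 19063 of these, several for 572, and did not list 11407. Each of 13438 genes was represented by its probe set with the highest mean over all arrays, among probe sets with 1 symbol; 3985 genes had more than 1 such probe set. Background was read on each array as the highest nonspecific control probe set, which lay between 3.88 and 4.18. Where at least 2 of the 3 arrays of the lower group lay at background, the fold is given as a lower bound against that level, and no fold is given where both groups did. No fold is given for Ctsh, which read near background in most arrays. A group mean less than 0.5 (log2) above background was taken as near it, a limit chosen after the results were seen, and folds against such groups are compressed; this holds for Rac2 at 0 h. Differences between responses that rest on a group at or near background are listed in the closing part as fitted values, which are not sizes.

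The test was limma (3.58.1, in R 4.3.3), with lmFit and eBayes at default settings in 1 model of 7 group means over 21 arrays. It gave 12 comparisons, among them the differences between the clones' responses at 6 and 16 h. All limma tests were two-sided, with Benjamini-Hochberg adjustment within a comparison over the 31042 probe sets and a threshold of 0.05. Values after ± are standard errors of this model unless SD is written. The model takes the spread of a probe set as equal in all groups, but replicate arrays lay further apart at 16 h than at 6 h. The SD of the difference between 2 replicates was 0.239 to 0.311 against 0.195 to 0.213 in pCTSH#1. In pcDNA it was 0.237 to 0.281 against 0.194 to 0.216. Standard errors at 16 h may therefore be too small, and calls there too many. The 25 gene lists were tested with camera (limma), which compares the members of a list with all other genes, at a preset correlation of 0.01 and adjusted over the 25 lists. The results of 1 of these lists are not reported here. The same test was run with a correlation estimated from the residuals. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

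The comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule allowed the 10 highest and 10 lowest genes with an adjusted p below 0.05 and no overlap between the 3 arrays of each group in the main comparisons, and the 5 highest and 5 lowest in the others. It also allowed up to 4 members of each list, and always gave 5 genes: Ctsh, Rac2, Nos2, Ins1 and Ins2. Symbols that are only locus numbers were left out. The text leaves out some genes that the rule allowed, mostly genes whose call ended when 1 array was left out.

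Alternatives were the replicate number as a block, arrays centred on their medians, cyclic loess, the brighter 50% of probe sets, eBayes with trend and robust settings, array weights, a fit on only the arrays compared, the mean of all probe sets of a gene, the estimated correlation, and leaving out each array in turn. Leaving out arrays and centring them for the lists, and leaving out the genes of the runs described in the closing part, were chosen after the results were seen. The planned pseudocount was not needed, since the values were on a log scale.

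Whether the replicate numbers pair the arrays was checked on the residuals. All 3 correlations between arrays of equal number were above 0.1 in 2 of 21 pairs of groups (INS1 with pcDNA, and pcDNA with pCTSH#1, both at 0 h), and the full range was -0.0903 to 0.244. Of 126 choices of the best match in another group 79 fell on the own number, where 42 would by chance, a hint from the data that equal numbers share something. Since the labels do not state it and few pairs of groups passed, the numbers were used as a block only as an alternative. The block gave 644, 963 and 1357 probe sets for the clones at 0, 6 and 16 h in place of 582, 887 and 1181, and 35 and 77 for the responses at 6 and 16 h in place of 32 and 66.

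The method was tested on simulated data. For 1 clone comparison, changes of log2 0.5 were recovered for 51% of 100 probe sets, changes of 1 for 94% of 50 and changes of 2 for 100%, with 5 false among 153 calls. For a difference between responses the shares were 22%, 80% and 100%, with 10 false among 122 calls. With 3 arrays per group, small differences can therefore be missed. The changed probe sets were drawn from the brighter ones only, and the noise was drawn independently for each probe set. These shares therefore do not hold for dim probe sets, where changes are compressed. Genes were placed along the chromosomes with the GRCr8 gene table, in which the Entrez identifiers of 18989 probe sets were found. No pair of arrays was identical.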

Results

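INS-1, a rat insulinoma line used as a model of the pancreatic beta cell, was studied in 7 groups of 3 arrays. The groups were untransfected cells without cytokines (INS1) and 2 transfected lines, each at 0, 6 and 16 h with IL-1β and IFNγ. The names follow the description of the series (the sample titles write pCTSH1): pcDNA carried the empty vector, and pCTSH#1 was a clone transfected with the lysosomal protease cathepsin H. Array medians lay between 4.88 and 5.08 (log2), and 61.4% to 71.0% of probe sets were above background. Mean correlations with the other arrays of the group were 0.993 to 0.997. The first principal component held 63.3% of the variance and the second 22.1%. The number of arrays, 3 per group, limits the precision of every value.

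The overexpressed gene was checked first. Ctsh (Entrez 25425, 1 probe set) read near background without cytokines in pCTSH#1 (log2 level 4.0) and pcDNA (3.9). The levels were 4.07 and 3.67 at 6 h and 4.45 and 3.79 at 16 h, too near background for a fold. The difference between the clones passed the test at none of these times (adjusted p = 0.945, 0.458 and 0.08, limma). Without replicate 1 of pcDNA or replicate 3 of pCTSH#1 at 16 h, the adjusted p for Ctsh at 16 h was 0.0326 and 0.0424. Both fits kept replicate 1 of pCTSH#1, which read 5.08, while replicates 2 and 3 read 4.15 and 4.11. The difference at 16 h thus rests largely on 1 array. The labels do not state the species of the transfected CTSH sequence or whether its transcript holds the sequence of this rat probe set, so these values do not check the label.

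The first question was how the empty vector line responded to 6 h of cytokines. No untreated arrays were made at 6 or 16 h. Changes from 0 h, here called responses, can therefore not be told apart from effects of time in culture or handling. Genes of chemokines, which attract leukocytes, were among those that rose: Cxcl2 by 8.09 ± 0.14 on the log2 scale (n = 3 per group, limma), Cxcl1 at least 508-fold, Cxcl9 at least 225-fold and Cxcl3 at least 171-fold. Genes of the antiviral interferon response rose with them, such as Isg15 (7.44 ± 0.10), Rsad2 (7.22 ± 0.10), Gbp2 (7.29 ± 0.16) and Ifih1 (2.84 ± 0.19). Nkx6-1, a transcription factor that maintains beta-cell identity, fell by 3.14 ± 0.16. Nos2, the inducible nitric oxide synthase, rose at least 7.83-fold. Rac2 (Entrez 366957), a gene best known from blood cells, rose by 0.65 ± 0.19 (adjusted p = 0.0111), a call lost without replicate 1 of pcDNA at 0 h (0.0585) or replicate 3 at 6 h (0.0956). Ins1 (-0.05 ± 0.06) and Ins2 (-0.20 ± 0.08), the rat insulin genes, did not pass (adjusted p = 0.612 and 0.0742), and Ctsh was at background at both times.

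All 40 measured interferon target genes rose at 6 h (camera adjusted p = 2.27e-50). Of 32 NF-kB target genes 26 rose (3.74e-28), among them the adhesion gene Icam1 (6.78 ± 0.14), Birc3, an inhibitor of apoptosis (5.44 ± 0.20), and Sod2, the mitochondrial superoxide dismutase (1.95 ± 0.08). In the list of MHC class I and the immunoproteasome, which makes and presents peptides, 15 of 19 rose (5.13e-17), such as Tap1 (5.35 ± 0.10) and Psmb9 (3.75 ± 0.09). MHC class II had 7 up and 1 down of 9 (1.36e-06; adjusted p = 0.0974 with an estimated correlation), with Cd74 at least 65.2-fold and RT1-Da at least 34.5-fold higher. AP-1 and immediate early genes rose for 23 and fell for 3 of 38 (7.88e-12), including Jun (4.28 ± 0.18), Egr1 (4.09 ± 0.11) and Atf3 (5.16 ± 0.12), which lies in a run of neighbouring genes that read higher in pCTSH#1. Pro-apoptotic genes rose for 11 and fell for 7 of 31 (0.00746; adjusted p = 0.0974 with an estimated correlation), with the death receptor Fas at 4.49 ± 0.12 and Bid at 3.00 ± 0.10. Type 1 diabetes candidate genes, a list that holds Rac2 and so is not independent of what the study chose, rose for 8 and fell for 2 of 27 (0.0083).

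Lists of beta-cell function, cholesterol synthesis, the cell cycle and mitochondrial metabolism were called lower at 6 h, calls not kept with an estimated correlation. Beta-cell transcription factors fell for 11 and rose for 2 of 17 (adjusted p = 0.00209, and adjusted p = 0.115 with an estimated correlation), with Isl1 at -2.10 ± 0.23, Nkx2-2 at -1.99 ± 0.17 and Foxa2 at -1.34 ± 0.08. Genes of insulin synthesis and secretion fell for 13 and rose for 1 of 35 (0.0083; adjusted p = 0.221 with an estimated correlation), such as the vesicle GTPase Rab3a (-1.92 ± 0.11) and the incretin receptor Glp1r (-0.92 ± 0.12). Cholesterol synthesis fell for 14 of 19 (0.00349; adjusted p = 0.503 with an estimated correlation), with Fdft1 at -1.32 ± 0.27, Insig1, a regulator of the pathway, at -1.21 ± 0.27 and Sqle at -1.16 ± 0.15. Cell cycle genes fell for 23 and rose for 4 of 50 (0.00209; adjusted p = 0.221 with an estimated correlation), including Rrm2 (-0.76 ± 0.09) and Uhrf1 (-0.85 ± 0.09). Mitochondrial energy metabolism fell for 16 and rose for 1 of 38 (0.00349; adjusted p = 0.221 with an estimated correlation). Outside these lists, Slc35d3 (-3.07 ± 0.18), Tmem100 (-2.95 ± 0.24), the calcium-sensing receptor Casr (-2.87 ± 0.20) and the adenosine receptor Adora2b (-2.84 ± 0.16) fell. Adjusted over the list alone, 29 cell cycle genes, 17 mitochondrial genes and 15 genes of insulin synthesis and secretion fell and 24 AP-1 genes rose, with the other counts equal. The calls of the interferon, NF-kB, MHC class I, AP-1 and type 1 diabetes lists held with an estimated correlation (adjusted p = 0.0285 or lower). Of 31042 probe sets, 3757 rose and 5734 fell; after cyclic loess 8740 were called and 51.6% of them rose, against 39.6%.

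At 16 h the question was which changes lasted and which were added in the empty vector line. Cxcl9 (at least 203-fold), Rsad2 (7.89 ± 0.10), Cxcl1 (at least 186-fold) and Cd74 (at least 195-fold) were far above their levels at 0 h. Stress genes were also above them: Trib3, a pseudokinase induced by unfolded proteins, by 6.53 ± 0.19, Chac1, which degrades glutathione, by 5.37 ± 0.13, and Ddit3, the stress factor CHOP, by 4.82 ± 0.10. Chac1 (2.66 ± 0.13) and Ddit3 (1.95 ± 0.10) had already risen at 6 h. Synpo2 (-4.47 ± 0.16), Tmem100 (-3.99 ± 0.24), the fatty acid elongase Elovl6 (-3.69 ± 0.22) and the monoamine oxidase Maob (-3.64 ± 0.11) fell. Rac2 rose by 1.54 ± 0.19 and Nos2 at least 1.53-fold, while Ctsh did not pass (adjusted p = 0.725). Ins2 fell by 0.63 ± 0.08. The smaller value of Ins1 (-0.15 ± 0.06, adjusted p = 0.0484) lost its call whichever of the 6 arrays was left out: the adjusted p was 0.159, 0.0856 and 0.0505 without replicates 1, 2 and 3 at 0 h, and 0.09, 0.0979 and 0.0762 without those at 16 h. It was 0.011 (adjusted p = 0.906) after cyclic loess.

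Of the interferon target genes 39 of 40 rose at 16 h (5.68e-24), of the NF-kB targets 25 of 32 (1.47e-13), and of MHC class I and the immunoproteasome 15 of 19 (6.97e-11). MHC class II rose for 8 and fell for 1 of 9 (5.42e-05; adjusted p = 0.149 with an estimated correlation). Endoplasmic reticulum stress genes rose for 18 and fell for 8 of 33 (9.04e-04; adjusted p = 0.221 with an estimated correlation), and pro-apoptotic genes rose for 16 and fell for 5 of 31 (0.0174; adjusted p = 0.135 with an estimated correlation), with Bbc3, which encodes PUMA, at 3.39 ± 0.11. Cell cycle genes fell for 45 and rose for 2 of 50 (2.34e-13), a call kept with an estimated correlation (adjusted p = 0.00772), with the mitotic genes Plk1 at -2.17 ± 0.08, Cdc20 at -2.13 ± 0.08 and Kif20a at -1.97 ± 0.09. Mitochondrial energy metabolism fell for 28 and rose for 4 of 38 (9.95e-05; adjusted p = 0.0998 with an estimated correlation), with Pdhb, a subunit of pyruvate dehydrogenase, at -1.56 ± 0.09 and Mpc2, which carries pyruvate into mitochondria, at -1.56 ± 0.08. Insulin synthesis and secretion fell for 21 and rose for 5 of 35 (0.00872; adjusted p = 0.221 with an estimated correlation), among them the exocytosis genes Sytl4 (-3.63 ± 0.17) and Rab27a (-2.81 ± 0.12). Neuronal markers fell for 14 and rose for 3 of 27 (0.0101), also with an estimated correlation (adjusted p = 0.0305), with Cplx2 at -2.38 ± 0.09. Beta-cell transcription factors fell for 11 and rose for 3 of 17 without a call of the list (adjusted p = 0.0511; 0.0459 without replicate 1 at 16 h, 0.0398 without replicate 2 at 0 h). Isl1 (-3.56 ± 0.23), Nkx6-1 (-3.01 ± 0.16) and Pdx1 (-1.99 ± 0.08), which lies in a run of neighbouring genes with a higher median in pCTSH#1, fell. Adjusted over the list alone, 9 endoplasmic reticulum stress genes and 29 mitochondrial genes fell, with the other counts equal, and the interferon, NF-kB and MHC class I calls held with an estimated correlation (adjusted p = 1.23e-04 or lower). In all, 6598 probe sets rose and 7801 fell.

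Between 6 and 16 h genes of pcDNA moved both ways. Tnf fell by 5.05 ± 0.18, Egr1 by 4.61 ± 0.11, Ifit2 by 3.98 ± 0.20, Socs1, a feedback inhibitor of cytokine signalling, by 3.12 ± 0.13, and Nos2 by 2.35 ± 0.18. Trib3 (5.31 ± 0.19), the p53 target Tp53inp1 (4.82 ± 0.20), the transcription factor Nfil3 (4.14 ± 0.12), Ddit3 (2.87 ± 0.10) and Rac2 (0.89 ± 0.19) rose. Ins2 fell by 0.43 ± 0.08, and Ins1 (-0.10 ± 0.06) and Ctsh (adjusted p = 0.696) did not pass. Interferon targets fell for 25 and rose for 4 of 40 (5.04e-04; adjusted p = 0.0962 with an estimated correlation), endoplasmic reticulum stress genes rose for 18 and fell for 4 of 33 (1.14e-04; adjusted p = 0.167 with an estimated correlation), and cell cycle genes fell for 40 and rose for 2 of 50 (4.34e-12; adjusted p = 0.0396 with an estimated correlation). MHC class II rose for 8 and fell for 1 of 9 (median 1.49, 0.00947; adjusted p = 0.343 with an estimated correlation). MHC class I and the immunoproteasome rose for 10 and fell for 2 of 19, at the threshold (0.05; adjusted p = 0.104 with an estimated correlation). That list was not past it without replicates 1, 2 or 3 of pcDNA at 6 h (0.0563, 0.0597, 0.0581) or replicates 1 or 3 at 16 h (0.0644, 0.078). Adjusted over the list alone, cell cycle genes fell for 42 and rose for 3, 13 MHC class I and immunoproteasome genes rose, and the other counts were equal. In all, 6281 probe sets rose and 6834 fell.

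The CTSH clone responded to the same cytokines in much the same genes. At 6 h Cxcl1 rose at least 467-fold, Cxcl9 at least 223-fold, Nos2 at least 5.97-fold, Nox1, the catalytic subunit of a superoxide-producing oxidase, by 2.03 ± 0.18, and Rac2 by 1.28 ± 0.19. Nkx6-1 fell by 2.97 ± 0.16 and Casr by 2.94 ± 0.20, while Ins1 (-0.03 ± 0.06), Ins2 (-0.06 ± 0.08) and Ctsh (adjusted p = 0.874) did not pass. At 16 h Cd74 was at least 250-fold higher than at 0 h, and Trib3 (6.55 ± 0.19), Chac1 (5.29 ± 0.13), Nox1 (3.57 ± 0.18), Rac2 (3.00 ± 0.19) and Nos2 (at least 2.34-fold) rose. Synpo2 (-4.09 ± 0.16), Vsnl1 (-3.86 ± 0.15), Nkx6-1 (-3.78 ± 0.16) and Plk1 (-2.11 ± 0.08) fell at 16 h. Ins2 did not pass (-0.18 ± 0.08, adjusted p = 0.0918). The call of Ins1 (-0.17 ± 0.06, adjusted p = 0.0248) was lost without replicate 1 of pCTSH#1 at 0 h (0.0845) or replicate 2 at 16 h (0.105). Ctsh (adjusted p = 0.0783) passed without replicate 2 or 3 at 16 h (0.0317 and 0.0235), in fits that kept replicate 1, whose Ctsh level was the highest. Interferon targets rose for 39 of 40 at 6 h (8.19e-55) and at 16 h (1.01e-25), and cell cycle genes fell for 45 and rose for 3 of 50 at 16 h (4.02e-13; adjusted p = 0.00831 with an estimated correlation). The calls numbered 8304 at 6 h and 14413 at 16 h, and pcDNA shared 7123 and 12431 of them in direction, with 3 and 15 opposite.

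**Figure D1:**
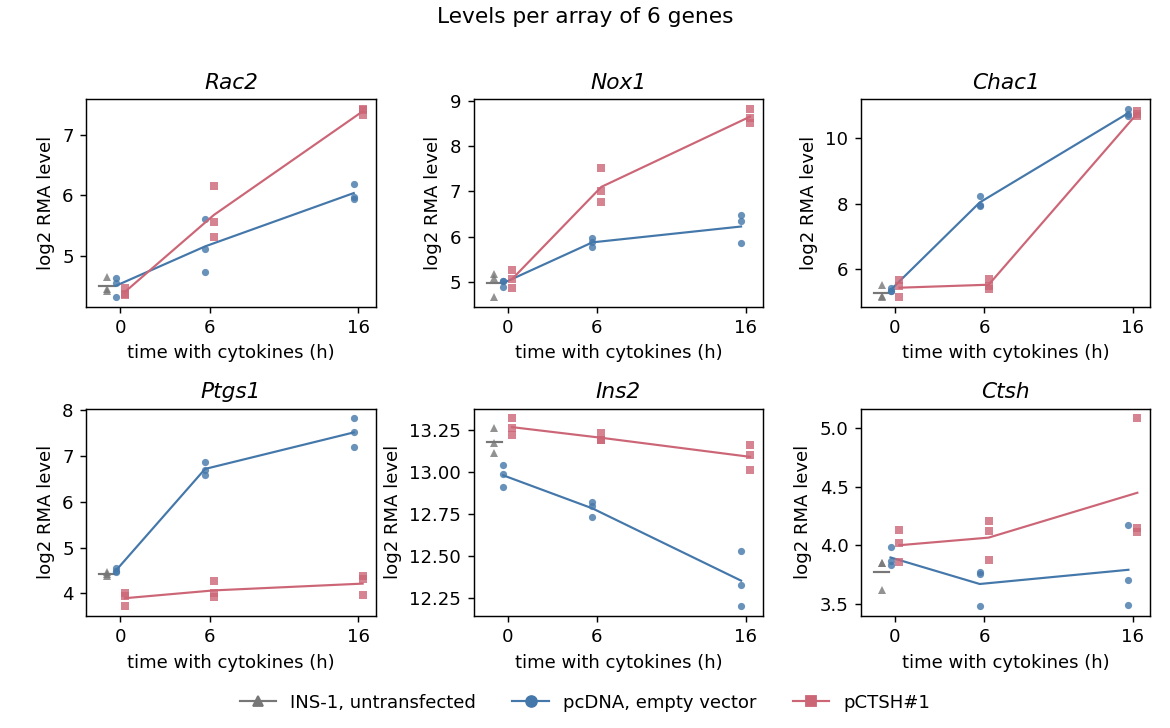
Log2 RMA level (y axis) of 6 genes against the time with cytokines in hours (x axis), with a point for each array and a line through the mean of each group of 3. Rac2 averages 7.40 in pCTSH#1 and 6.04 in pcDNA at 16 h, and Ptgs1 differs there by -3.31.

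Before any cytokine, pCTSH#1 differed from pcDNA in genes of several functions. Gna15, a G protein subunit best known from blood cells, was 14.2-fold higher in pCTSH#1 (log2 3.83 ± 0.12, n = 3 per group, adjusted p = 1.4e-13), Ttn, the muscle protein titin, at least 5.92-fold, and the phospholipid flippase gene Atp10a 6.75-fold (2.75 ± 0.13). Tac1, the precursor of substance P (-2.07 ± 0.12), and Tesc, which encodes the calcium-binding tescalcin (-2.04 ± 0.12), were lower in pCTSH#1. Also higher were Gas7 (2.59 ± 0.13), Islr2 (1.81 ± 0.16), Fam151a (1.58 ± 0.11), the corepressor Runx1t1 (1.57 ± 0.14), Naprt, an enzyme of NAD synthesis (1.54 ± 0.17), Aldh1a1, which makes retinoic acid (1.39 ± 0.10), Polr3g (1.25 ± 0.11), the neuropeptide Npy (1.08 ± 0.09) and Stx1a, an exocytosis gene in a run of neighbouring higher genes (0.71 ± 0.11). Also lower were Myo16 (-1.68 ± 0.14), the sialyltransferase St6gal1 (-1.51 ± 0.10), angiotensinogen, Agt (-1.48 ± 0.12), Rab34 (-1.47 ± 0.12), the myelin gene Pmp22 (-1.35 ± 0.14), the trefoil factor Tff3 (-1.24 ± 0.17), Serpine2 (-1.22 ± 0.16) and Fas (-0.87 ± 0.12). Rac2 (-0.10 ± 0.19, adjusted p = 0.942), Ins1 (-0.01 ± 0.06) and Ins2 (0.28 ± 0.08, adjusted p = 0.105) did not pass, and Nos2 was at background in both clones.

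Of MHC class I and immunoproteasome genes 5 of 19 were lower in pCTSH#1 at 0 h, 6 adjusted over the list alone (camera adjusted p = 1.15e-04, and adjusted p = 0.00506 with an estimated correlation), among them Psmb8 (-0.72 ± 0.08), Tap1 (-0.58 ± 0.10) and Tap2 (-0.55 ± 0.11). Lysosomal genes had 1 lower and 36 not passed of 37, the protease Lgmn (-0.53 ± 0.09), with 1 higher and 4 lower adjusted over the list alone; the list was called lower (0.0234, and adjusted p = 0.0344 with an estimated correlation), except without replicate 2 of pcDNA (0.0669). Endoplasmic reticulum stress genes had 1 higher, none lower and 32 not passed, and the list was called lower at an adjusted p of 0.0326, though adjusted p = 0.631 with an estimated correlation. That call was also lost without replicate 1 or 2 of pcDNA (0.302, 0.0669) or replicate 3 of pCTSH#1 (0.407). In all, 356 probe sets were higher and 226 lower, 582 together (384 without replicate 1 of pcDNA, 284 in a fit of only these 6 arrays). The 3 arrays of each group did not overlap for 15.7% of probe sets, where 10% would by chance.

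The untransfected cells served to ask in which line these genes differed. Against INS1, pCTSH#1 had Gna15 at 4.06 ± 0.12, Ttn at least 6.12-fold higher, Atp10a at 3.06 ± 0.13, Gas7 at 2.56 ± 0.13, Tesc at -1.94 ± 0.12, Tac1 at -1.87 ± 0.12 and Tff3 at -1.64 ± 0.17. The glucagon gene Gcg, which is not among the genes named above for the clones, was at 1.28 ± 0.17. Fas (-0.85 ± 0.12), Tap1 (-0.57 ± 0.10) and Psmb8 (-0.55 ± 0.08) were lower here too. Rac2 (-0.11 ± 0.19), Ctsh (adjusted p = 0.755), Ins1 (-0.04 ± 0.06) and Ins2 (0.08 ± 0.08) did not pass, and Nos2 was at background. MHC class I and the immunoproteasome had 3 of 19 lower (2 higher and 6 lower adjusted over the list alone), and its adjusted p of 0.0596 became 0.0474, 0.0323 and 0.0333 without replicate 1 or 3 of INS1 or replicate 1 of pCTSH#1. In all, 531 probe sets were higher and 266 lower, 797 together, or 366 in a fit of only these 6 arrays. Between pcDNA and INS1 limma called 3 probe sets and 0 named genes, with 1542 probe sets at an unadjusted p below 0.05, and none of Rac2 (-0.00 ± 0.19), Ins1 (-0.03 ± 0.06), Ins2 (-0.20 ± 0.08), Ctsh and Nos2 (both at background) passed.

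After 6 h of cytokines Chac1 (-2.50 ± 0.13, n = 3 per group, adjusted p = 7.97e-10) and Ptgs1, the constitutive cyclooxygenase (at least 6.04-fold, adjusted p = 1.04e-09), were lower in pCTSH#1 than in pcDNA. Endoplasmic reticulum stress genes were lower for 11 of 33, and adjusted over the list alone 1 was higher and 12 lower (camera adjusted p = 9.76e-12, and adjusted p = 0.0384 with an estimated correlation). They included Trib3 (-1.30 ± 0.19), Herpud1, which helps degrade misfolded proteins (-1.07 ± 0.14), and Eif2ak3, the stress kinase PERK (-0.92 ± 0.15). NF-kB targets were lower for 2 of 32, 6 adjusted over the list alone (1.46e-04, and adjusted p = 0.0384 with an estimated correlation), with Ptgs2, the inducible cyclooxygenase, at -1.17 ± 0.17 and the chemokine Ccl20 at -0.70 ± 0.10. Interferon targets had 1 lower of 40, Oasl (-1.88 ± 0.21), also 1 adjusted over the list alone (0.0103; adjusted p = 0.292 with an estimated correlation). Cell cycle genes had 1 higher of 50 and the list was called higher (0.00965; adjusted p = 0.358 with an estimated correlation, and 0.0689 without replicate 3 of pcDNA).

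Other genes lower at 6 h were Tesc (-1.88 ± 0.12), Tac1 (-1.81 ± 0.12), the B-cell adaptor Blnk (-1.75 ± 0.25), Rab34 (-1.65 ± 0.12), the complement gene C9 (-1.59 ± 0.17), St6gal1 (-1.49 ± 0.10), Onecut1 (-1.16 ± 0.18), the inflammatory caspase Casp4 (-1.02 ± 0.16), Ddit4, an inhibitor of mTORC1 (-0.94 ± 0.09), Myc (-0.79 ± 0.09) and fibronectin, Fn1 (-0.77 ± 0.11). Higher were Gna15 (3.23 ± 0.12), Atp10a (2.24 ± 0.13), Naprt (1.94 ± 0.17), Islr2 (1.72 ± 0.16), Fam151a (1.46 ± 0.11), Polr3g (1.41 ± 0.11), Glod5 (1.34 ± 0.09), the sarcomere gene Ldb3 (1.24 ± 0.18), Nox1 (1.22 ± 0.18), Npy (1.11 ± 0.09), Glp1r (0.94 ± 0.12), Sytl4 (0.83 ± 0.17) and Ins2 (0.42 ± 0.08, adjusted p = 0.00495). Rac2 did not pass (0.52 ± 0.19, adjusted p = 0.199; 0.0343 without replicate 3 of pcDNA), nor did Ctsh (0.458), Nos2 (-0.37 ± 0.18, adjusted p = 0.425) or Ins1 (0.01 ± 0.06). The 3′ minus 5′ signal of actin, a measure of RNA integrity, was 0.804 ± 0.077 in pCTSH#1 and 0.941 ± 0.022 in pcDNA (SD, n = 3). That of GAPDH was -0.221 ± 0.047 in pCTSH#1 and -0.204 ± 0.052 in pcDNA (SD, n = 3). In all, 544 probe sets were higher and 343 lower, 887 together, and 1737 were called with array weights. Without replicates 1 and 2 of pcDNA in turn 591 and 574 were called, and without replicates 1 and 2 of pCTSH#1 542 and 531. The groups did not overlap for 22% of probe sets, where chance gives 10%.

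At 16 h Rac2 was 2.56-fold higher in pCTSH#1 than in pcDNA (log2 1.36 ± 0.19, n = 3 per group, adjusted p = 2.31e-04), at levels of 7.40 and 6.04. Nox1 was 5.34-fold higher (2.42 ± 0.18, adjusted p = 1.27e-07). Lower were Ptgs1 (-3.31 ± 0.14, adjusted p = 5.82e-11, with pCTSH#1 near background at 4.21), Cyria (at least 4.28-fold), Ppargc1a, the coactivator of mitochondrial genes (at least 3.56-fold), and Spry2, an inhibitor of growth factor signalling (-1.80 ± 0.13). Ins2 was higher (0.74 ± 0.08, adjusted p = 1.96e-05) and Ins1 was not (-0.03 ± 0.06, adjusted p = 0.873). The arrays of pCTSH#1 read 13.01 to 13.16 for Ins2, near the array maxima of 13.69 to 13.99. Whether saturation compressed differences of the insulin genes was not tested. Nos2 did not pass (0.63 ± 0.18, adjusted p = 0.0543), but did without replicate 1 of pCTSH#1 (0.00909) or replicate 2 of pcDNA (0.0111). Other higher genes were Atp10a (2.56 ± 0.13), the caveola protein gene Cav1 (1.86 ± 0.18), Ldb3 (1.75 ± 0.18), Fam151a (1.58 ± 0.11), Naprt (1.46 ± 0.17), the actin-binding Cotl1 (1.45 ± 0.12), Glod5 (1.40 ± 0.09), Npy (1.18 ± 0.09) and Gna15 (at least 2.5-fold). Other lower genes were C9 (-1.76 ± 0.17), Tac1 (-1.65 ± 0.12), Rab34 (-1.57 ± 0.12), Tesc (-1.52 ± 0.12), the chemokine scavenger Ackr3 (-1.44 ± 0.15), Blnk (-1.42 ± 0.25), the vesicle gene Syt4 (-0.69 ± 0.10), the BH3-only gene Hrk (-0.64 ± 0.12) and the lysosomal protease Ctsl (-0.51 ± 0.07).

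Interferon targets were higher for 3 and lower for 1 of 40 at 16 h, 5 and 1 adjusted over the list alone (camera adjusted p = 4.44e-06; adjusted p = 0.0697 with an estimated correlation), with Ifit2 at 1.03 ± 0.20, Ido1, which degrades tryptophan, at 1.05 ± 0.18, and Oasl lower at -1.08 ± 0.21. MHC class II had 1 higher of 9, 4 adjusted over the list alone (4.75e-04; adjusted p = 0.217 with an estimated correlation), the transactivator Ciita (0.70 ± 0.11). Endoplasmic reticulum stress genes were lower for 3 of 33, 5 adjusted over the list alone (5.79e-05; adjusted p = 0.187 with an estimated correlation). NF-kB targets were higher for 3 of 32, 7 higher and 2 lower adjusted over the list alone (0.0355; adjusted p = 0.187 with an estimated correlation), the chemokines Cxcl2 (0.80 ± 0.14), Cxcl3 (0.68 ± 0.08) and Cxcl1 (0.52 ± 0.11). That call was lost without replicate 2 or 3 of pCTSH#1 (0.0502, 0.174) or replicate 3 of pcDNA (0.11), as was that of the cell cycle genes, with 1 higher of 50 (0.0355; 0.0948, 0.174 and 0.0713; adjusted p = 0.443 with an estimated correlation). Leukocyte markers had 1 higher of 23 and a median of 0.04 (adjusted p = 0.799), and type 1 diabetes candidate genes, which also hold Rac2, 2 higher of 27 (0.0955), a list that is therefore not independent evidence. The actin 3′ minus 5′ signal was 0.650 ± 0.048 in pCTSH#1 and 0.797 ± 0.060 in pcDNA (SD, n = 3). That of GAPDH went the other way, with -0.170 ± 0.037 in pCTSH#1 and -0.252 ± 0.026 in pcDNA (SD, n = 3). In all, 722 probe sets were higher and 459 lower, 1181 together (757 without replicate 2 of pcDNA, 193 in a fit of only these 6 arrays), and 17.1% did not overlap against 10% by chance.

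**Figure D2:**
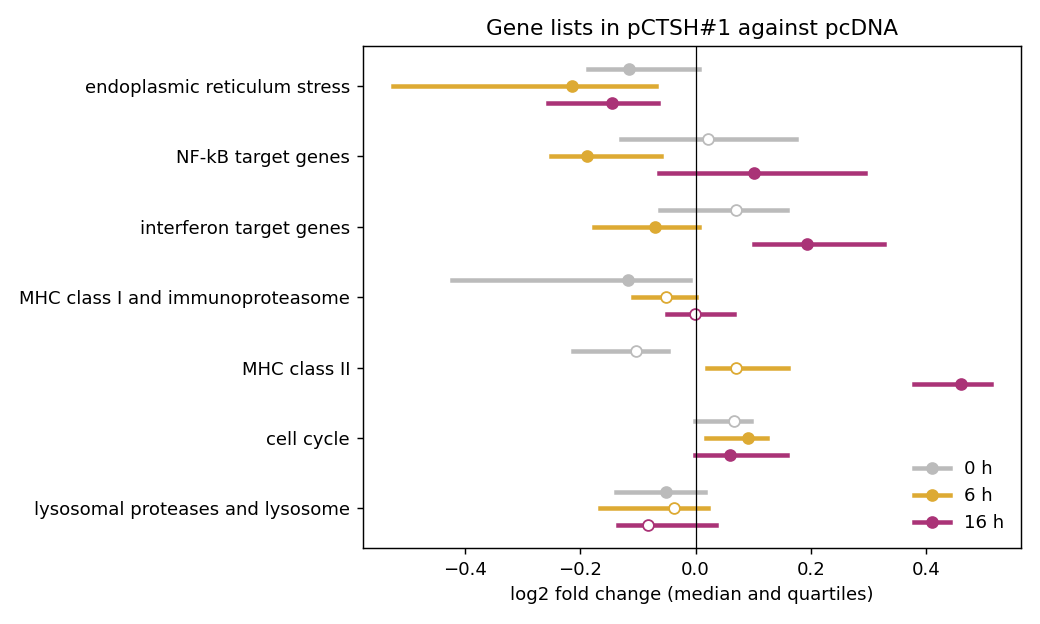
Median log2 fold change of pCTSH#1 over pcDNA (x axis) for gene lists (y axis) at 0, 6 and 16 h, with lines from the lower to the upper quartile of the members. Filled points had a camera adjusted p below 0.05 and open points did not; endoplasmic reticulum stress genes had medians of -0.12, -0.21 and -0.15, and MHC class II 0.46 at 16 h.

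Some differences between the clones were found at all 3 times. These were 155 probe sets higher (99 genes, such as Gna15, Atp10a, Fam151a and Npy) and 43 lower (33 genes, such as Tesc, Tac1 and Rab34), where 0.145 and 0.0369 would be called by chance if the comparisons were independent. Many of the 99 higher genes, Stx1a among them, lie in the runs of neighbouring genes described below. They are therefore not all separate differences, though Gna15, Atp10a, Fam151a and Npy lie outside the runs. A fit of only the arrays compared gave 53 in place of 198. Between pCTSH#1 against pcDNA at 6 h and pCTSH#1 against INS1 at 0 h, which share no arrays, 280 probe sets were higher in both, 96 lower in both and 2 opposite.

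Whether the clones responded differently to the cytokines was tested as the difference of their responses. At 16 h the response of Nox1 was larger in pCTSH#1 by 2.33 ± 0.25 on the log2 scale (adjusted p = 1.05e-04), and that of the immunoproteasome gene Psmb8 by 0.72 ± 0.11 (0.00572). Psmb8 started lower in pCTSH#1 at 0 h, so its larger response does not show a higher level at 16 h. The responses of Rac2 (0.0217) and Ciita (0.00544) were also called larger, but both genes read near background in pCTSH#1 at 0 h (Rac2 also in pcDNA, with levels of 4.40 and 4.50), so no size is given. At 6 h Chac1 (-2.57 ± 0.18, adjusted p = 4.55e-07) and Ddit3 (-0.91 ± 0.13) responded less in pCTSH#1. Of the 16 and 37 named genes called at 6 and 16 h, 6 and 14 had a group at or near background. Their fitted differences are not sizes and are not given here. The call of Rac2 at 16 h ended without replicate 1 or 3 of pCTSH#1 at 0 h (0.0647, 0.0525), replicate 2 or 3 of pCTSH#1 at 16 h (0.0555, 0.0581), replicate 2 or 3 of pcDNA at 0 h (0.0722, 0.0573) or replicate 1 of pcDNA at 16 h (0.052). Ins2 (0.46 ± 0.12, adjusted p = 0.148), Ins1 (-0.02 ± 0.09), Nos2 (0.223) and Ctsh (0.663), the last 2 with groups at background, did not pass at 16 h. Nox1 (1.13 ± 0.25, 0.134), Rac2 (0.777), Ins2 (0.14 ± 0.12), Ins1 (0.02 ± 0.09), Ctsh and Nos2 did not pass at 6 h. At 6 h, 6 probe sets responded more and 26 less in pCTSH#1, 32 together; 17 and 20 were called without replicates 1 and 2 of pCTSH#1 at 0 h, 20 without replicate 1 of pCTSH#1 at 6 h, and 19 without replicate 1 or 3 of pcDNA at 6 h. At 16 h, 39 responded more and 27 less, 66 together, or 36 without replicate 1 of pCTSH#1 at 0 h. Adjusted over the list alone, the response of 8 endoplasmic reticulum stress genes of 33 was smaller at 6 h, and 5 of 19 MHC class I and immunoproteasome genes responded more at 6 h and at 16 h. Adjusted over all probe sets fewer members passed, as given in the closing part. The call of the endoplasmic reticulum stress list was lost with an estimated correlation.

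Genes higher in pCTSH#1 lay close together in 2 stretches of the GRCr8 gene order, noticed after the values were seen. These runs were defined by the running median of the 0 h fold changes. Their medians and share of called genes at 0 h therefore follow in part from that choice, which the 6 and 16 h arrays did not enter. The run from Prr36 to Gusb, which also holds Stx1a and Pdx1, had a median log2 fold change of 0.25 over 160 brighter genes at 0 h, 0.29 at 6 h and 0.27 at 16 h. The run from Mpzl1 to Cr1l, which also holds Atf3, had medians of 0.36, 0.41 and 0.37 over 105 genes. A run took in all genes of the windows that passed, so genes near its ends need not be higher. Of the ends, Prr36 (-0.20), Gusb (-0.12) and Mpzl1 (-0.13) were not higher at 0 h, while Cr1l read 0.39. Pdx1, inside its run, stood at -0.04 at 0 h. Dim genes included, the runs held 384 of 13419 placed genes (2.86%) and 93 of the 210 genes higher at 0 h (44.3%), 120 of 327 at 6 h (36.7%) and 116 of 445 at 16 h (26.1%). Rac2, Nox1, Gna15 and Ins2 lie outside them.

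**Figure D3:**
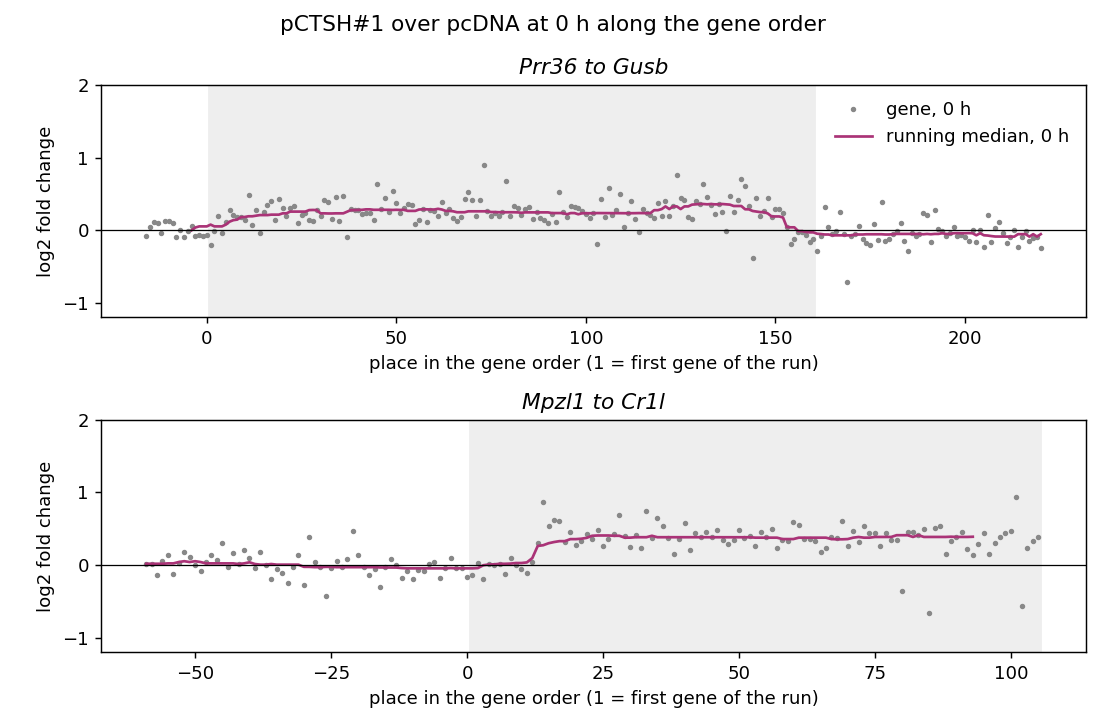
Log2 fold change of pCTSH#1 over pcDNA at 0 h (y axis) of single genes in their order along the GRCr8 assembly (x axis, place in the gene order), with the running median, around 2 runs of neighbouring genes (shaded). The y axis is limited to -1.2 to 2, with genes beyond it drawn at its edge. The run from Prr36 to Gusb has a median of 0.25 and that from Mpzl1 to Cr1l 0.36. The same 0 h values defined the runs, and genes near the ends of the shading need not be higher.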

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

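All tests of explanations given here were chosen after the results were seen. The share over all splits of the arrays was planned before, but the subsets of splits singled out below were not part of that plan.

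Differences between the clones' cytokine responses stood out. At 6 h, 32 probe sets responded differently, among them Chac1 (-2.57 ± 0.18), Ptgs1 (-2.05 ± 0.20), the growth arrest gene Gas7 (-1.29 ± 0.18), Ddit3 (-0.91 ± 0.13) and Mppe1 (1.00 ± 0.16), each given as the log2 response of pCTSH#1 minus that of pcDNA. The count was 17 and 20 without replicates 1 and 2 of pCTSH#1 at 0 h, 20 without replicate 1 of pCTSH#1 at 6 h, and 19 without replicate 1 or replicate 3 of pcDNA at 6 h. At 16 h, 66 probe sets differed, among them Nox1 (2.33 ± 0.25), Elmod1, a GTPase-activating protein (1.47 ± 0.23), Rac2 (1.46 ± 0.27), Ciita (1.02 ± 0.15), Psmb8 (0.72 ± 0.11), Ptgs1 (-2.70 ± 0.20), Gas7 (-2.41 ± 0.18), Gna15 (-2.40 ± 0.17), Cyria (-2.16 ± 0.24) and titin, Ttn (-1.93 ± 0.26). The count was 36 without replicate 1 of pCTSH#1 at 0 h. The values of Ptgs1, Gas7, Gna15, Cyria and Ttn rest on groups with at least 2 of 3 arrays at background. They are fitted values that fix neither the size nor the direction of the difference of response. Those of Rac2 and Ciita, near background in pCTSH#1 at 0 h, are fitted values as well. Of the 16 named genes called at 6 h 7 were called in each of the 12 fits that left out 1 array, and of 37 at 16 h 18 were. Rac2 was not among them: its adjusted p of 0.0217 rose to between 0.052 and 0.0722 without replicates 1 or 3 of pCTSH#1 at 0 h (0.0647, 0.0525), replicates 2 or 3 of pCTSH#1 at 16 h (0.0555, 0.0581), replicates 2 or 3 of pcDNA at 0 h (0.0722, 0.0573) or replicate 1 of pcDNA at 16 h (0.052), while its fitted value stayed between 1.39 and 1.45 in these 7 fits.

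By the planned share over all splits, chance was not excluded for these counts. Of 100 splits 8 gave as many probe sets at 6 h and 11 at 16 h, the real one included, with the highest other at 1445 and 1564. These large counts point to a structure of the samples: such splits exchange the clones at 1 time only, so that the lasting differences between the clones add up. Splits that kept the exchanged arrays even, so that lasting differences cancel, were a subset outside the plan. Among these, 1 of 37 reached the real 32 at 6 h (highest other 0) and 1 of 39 reached the real 66 at 16 h (highest other 4), in both cases the real split.

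By lists, NF-kB targets were called lower for the difference of response at 6 h (median -0.19, camera adjusted p = 6.95e-06, and adjusted p = 0.0226 with an estimated correlation), with 1 of 32 members passed. Interferon targets were also called lower (-0.14, 1.25e-05, and adjusted p = 0.0409 with an estimated correlation), with 1 of 40 passed, 2 adjusted over the list alone. So were endoplasmic reticulum stress genes (-0.078, 5.49e-07, but adjusted p = 0.0975 with an estimated correlation), with 2 of 33 passed, 8 adjusted over the list alone. Over all probe sets the 6 h response of pCTSH#1 had a slope of 0.879 on that of pcDNA. Lists that rose strongly in pcDNA are therefore drawn lower. Whether NF-kB and interferon targets went beyond this was not tested. MHC class I and the immunoproteasome were called higher at 6 h (0.067, 0.00375, and adjusted p = 0.0281 with an estimated correlation) and at 16 h (0.16, 1.51e-04, and adjusted p = 0.0077 with an estimated correlation), with 1 of 19 members passed at each time, 5 adjusted over the list alone; this list was lower in pCTSH#1 at 0 h. MHC class II was called higher at 16 h (0.59, 1.92e-05, but adjusted p = 0.273 with an estimated correlation; 1 of 9, 3 adjusted over the list alone). Its call at 6 h (0.17, 0.0226, but adjusted p = 0.654 with an estimated correlation) had 0 of 9 members passed, also 0 adjusted over the list alone, and was lost without replicate 1 or 2 of pcDNA at 6 h (0.118, 0.17) or replicate 3 of pCTSH#1 at 0 h (0.125) or 6 h (0.426). The call of interferon targets at 16 h (0.097, 0.00441, but adjusted p = 0.273 with an estimated correlation) had 0 of 40 passed, and adjusted over the list alone 5 higher and 2 lower; it was lost without replicate 1 of pcDNA at 16 h (0.0533).

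The first pattern was Rac2, at 1.36 in pCTSH#1 over pcDNA after 16 h. A single array was argued against, since the lowest value over the 6 fits that left out 1 array was 1.31 (without replicate 3 of pcDNA). A difference present before the cytokines stays open: Rac2 stood at -0.10 at 0 h, but both groups (4.40 and 4.50) were near background, where a difference is compressed. Leukocytes in the pCTSH#1 cultures were tested with 23 markers, whose upper quartile was 0.193, below Rac2. Most of these markers, such as Ptprc (3.84 in pcDNA and 3.59 in pCTSH#1), lay below background in both clones, where a difference is compressed. The quartile therefore cannot decide on leukocytes. Above background, Lcp1, with the highest array signal, was 9.58 in pcDNA and 9.76 in pCTSH#1, Cd68 5.52 and 5.89, and Lyz2 4.63 and 4.86. Laptm5 went the other way, with 4.65 and 4.49. These markers were named after their values were seen. Coro1a, which INS-1 cells express without cytokines, was higher (5.39 and 6.17, 0.78 ± 0.17, adjusted p = 0.013, but 0.076 and 0.078 without replicates 1 and 2 of pcDNA and 0.0679 without replicate 3 of pCTSH#1). No sort that would remove leukocytes is stated, and a list that holds Rac2 is no evidence, since the study names this gene. A larger induction of Rac2 in this clone may be a hypothesis, but with 1 clone the effect of CTSH was not tested apart from that of the clone.

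The second pattern was the 11 endoplasmic reticulum stress genes lower in pCTSH#1 at 6 h, with a median of -0.86. A smaller response over all genes was tested on 6 h arrays that did not enter the choice of genes: with 1 array of each clone held out in 9 ways, 7 to 9 genes were chosen, and their median of observed minus predicted on the held-out arrays lay between -0.915 and -0.384, which argues against it as the whole cause. A lower level before the cytokines was argued against as the whole cause by the median of these genes at 0 h, -0.167, read on arrays that did not enter their choice; it leaves room for a part. All 11 were still lower after cyclic loess, which argues against a difference between arrays left after RMA. Cyclic loess was run on values that RMA had already quantile normalized, so it cannot decide whether that earlier step played a part. A delayed stress response in this clone may be the cause, which was not tested, and CTSH and clone effects were not told apart by any test here.

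The third pattern was the 2 runs of neighbouring genes, 265 brighter genes with a median of 0.29 at 0 h, the time whose values defined the runs. At 16 h, whose arrays did not enter the choice, the median was 0.295. Chance position was argued against, since 0 of 1000 shuffles of the gene order gave as many windows of 25 genes with a running median beyond 0.2 as the real 217. A lower level in pcDNA was argued against by the median of pcDNA over INS1, 0.0476. Extra copies of these regions in pCTSH#1 are a candidate explanation, for which the median difference between the clones' 16 h responses, 0.0156, left the excess the same with and without cytokines. No DNA was measured, so copy number and a lasting change of regulation both stay open, and the calls of Stx1a and of other genes in the runs could follow from either.

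For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 582 and 1 for pCTSH#1 against pcDNA at 0 h, 887 and 1 at 6 h, and 1181 and 115 at 16 h. They were 9491 and 0 for pcDNA 6 h against 0 h, 14399 and 1 for 16 h against 0 h, 13115 and 0 for 16 h against 6 h, 8304 and 0 for pCTSH#1 at 6 h, and 14413 and 0 at 16 h. Against INS1 they were 3 and 0 for pcDNA and 797 and 3 for pCTSH#1. Where the numbers pair the arrays (pcDNA with pCTSH#1 and with INS1, at 0 h), the 3 other splits that part every pair gave at most 0. For the 198 probe sets that differed at all 3 times, 1 of 100 splits gave as many, the real one, and the highest other was 0. This argues against the spread between these arrays as the cause. The labels do not say whether replicates are separate cultures, so the splits do not decide on differences between cultures. Nor can they part an effect of CTSH from a difference of this clone.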

How the results depend on the processing

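Leaving out arrays or centring them for the lists, and leaving out the genes of the runs, were tests chosen after the results were seen; the other alternatives were planned. Of 4317 alternative values for the 301 gene results, 4250 kept their side of the threshold, 41 lost a call, 25 gained one and 1 reversed. Direction was compared only where the main fit or the alternative called the gene, so changes of sign without a call were not counted. The reversed value was Ins1 in pcDNA at 16 h, 0.011 after cyclic loess (adjusted p = 0.906, and over its alternatives from 0.0505 where 1 array was left out). Since most of these genes were named because their calls held when 1 array was left out, these counts do not measure stability. Of all named genes called for the responses, 7 of 16 at 6 h and 18 of 37 at 16 h held. Without the genes of the runs the genes called stayed within 1.5 times in each comparison. The higher ones went from 210 to 117, 327 to 207 and 446 to 330 for the clones at 0, 6 and 16 h and from 307 to 177 for pCTSH#1 against INS1. The lower ones went from 134 to 132, 209 to 207, 264 to 261 and 156 to 154.

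Counts of probe sets moved by more than 1.5 times as follows. With the brighter 50% of probe sets, 110 differed in response at 16 h and 1 between pcDNA and INS1, and the lists called numbered 4 for pcDNA 16 h against 6 h, 0 for pcDNA against INS1 and 1 for pCTSH#1 against INS1. With trend and robust settings the responses differed for 55 at 6 h and 120 at 16 h, and pcDNA and INS1 for 5. With array weights 1737 differed between the clones at 6 h, and 65 in response. A fit of only the arrays compared, which has fewer arrays to estimate the spread, gave 284 at 0 h, 193 at 16 h, 53 at all 3 times, 30 in response at 16 h, 0 for pcDNA against INS1 and 366 for pCTSH#1 against INS1. In that fit the count for the clones at 6 h, from as many arrays, did not move by more than 1.5 times. Fewer arrays alone therefore do not account for the drop at 16 h, where replicate arrays lay further apart. The causes of these moves were not tested.

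With an estimated correlation the lists called fell to 2 for the clones at 6 h and 0 at 16 h, 5 for pcDNA at 6 h, 5 at 16 h and 1 between these times, 5 for pCTSH#1 at 6 h and 5 at 16 h, 3 and 1 for the responses at 6 and 16 h, and 0 for pcDNA against INS1. With arrays centred pcDNA against INS1 had 0 lists, and with the mean of all probe sets pCTSH#1 against INS1 had 2.

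Leaving out 1 array gave 384 to 465 probe sets for the clones at 0 h, 531 to 646 at 6 h and 757 to 1250 at 16 h, and 17 to 30 and 36 to 77 for the responses at 6 and 16 h. The lists called ranged from 1 to 4, 3 to 5 and 3 to 7 for the clones at 0, 6 and 16 h, 0 to 3 for pcDNA against INS1 and 0 to 4 for pCTSH#1 against INS1. The median of cholesterol synthesis for pcDNA against INS1 ranged from -0.14 (without replicate 3 of INS1) to 0.18 (without replicate 3 of pcDNA, adjusted p = 0.00462), so that list was decided by single arrays. Signal over background limits Ctsh and Nos2, which lay near it in the untreated cells.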

Other observations

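No explanation was tested for these values; leaving out arrays for the lists was a test chosen after the results were seen. Several lists without a call held genes that moved with cytokines in pcDNA, in most of these lists both ways. Of 38 genes of oxidative stress defence and nitric oxide metabolism, 11 rose and 13 fell at 16 h (camera adjusted p = 0.941, with a median of -0.02 and a mean of 0.12), among them Ass1, which remakes arginine for nitric oxide synthesis (3.71 ± 0.14). Anti-apoptotic genes rose for 9 and fell for 5 of 18 at 16 h (0.0762), and Mcl1 had risen by 1.63 ± 0.08 at 6 h. Of the mesenchymal and endothelial markers 6 of 26 rose and 3 fell at 6 h (0.254), with the filament gene Vim at least 10.1-fold higher. Other islet endocrine markers fell for 4 of 17 at 16 h (0.496), such as glucagon, Gcg (-2.34 ± 0.17). Leukocyte markers rose for 4 and fell for 1 of 23 at 16 h (0.527), with Cd68 at 0.83 ± 0.19 and Coro1a, which INS-1 cells express before treatment (level 7.31), at -1.92 ± 0.17. Glycolysis and hypoxia genes rose for 10 and fell for 10 of 33 (0.616).

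Across all 31042 probe sets the responses of the clones were close, with a Pearson correlation of 0.949 at 6 h and 0.966 at 16 h (Spearman 0.769 and 0.883). Probe sets are not independent replicates, so no p-value is given. The spread of the response in pCTSH#1 was 0.927 times that in pcDNA at 6 h and 0.998 times at 16 h.

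Between pcDNA and INS1, where limma called 3 probe sets, MHC class I and the immunoproteasome had a median of 0.08 (adjusted p = 0.032, but adjusted p = 0.0689 with an estimated correlation), with 0 of 19 members past the test and also 0 adjusted over the list alone. The call was lost without replicates 1 or 3 of INS1 (0.329, 0.0996) or replicates 1 or 2 of pcDNA (0.0548, 0.235). Neuronal markers had a median of -0.05 (adjusted p = 0.032, but adjusted p = 0.0689 with an estimated correlation), lost without replicates 1 or 2 of INS1 (0.227, 0.087) or replicates 1 or 3 of pcDNA (0.0501, 0.298).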
